A study of Mus musculus with 2 samples.

How the data were processed

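The series holds 2 droplet single-cell RNA-seq libraries of whole mouse prostate, 1 per group. Both mice carried a tamoxifen-inducible Cre recombinase at the Nkx3-1 locus, conditional alleles of Pten and Trp53, and a Cre-dependent EYFP reporter that marks recombined cells and their progeny. The group NPp53T also carried conditional alleles of Trim28. Per the labels, tamoxifen was given by gavage at 200 mg/kg for 4 days at 2 months of age, and tissue was collected 1 month later, at 3 months. The tissue was digested with papain and filtered. About 6000 cells per library were loaded on a 10x Genomics Chromium instrument and read from the 3' ends of transcripts.

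The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, made by the authors with Cell Ranger 5.0.1 against genome build mm10, per the submitters' processing notes. The feature table had 32286 entries, with YFP added to the mouse genes, and the lowest UMI count of a barcode was 500. Barcode calling, the alignment and the counting were the authors'. Other settings are not given in the sources used here, and how reads of near-identical genes were assigned is therefore unknown. Values of families with near-identical members (Stfa and Cstdc, Scgb, Gsdmc, Sprr2, Bglap, Ifit3, Gzm and the H2 class I genes) are uncertain for this reason. Gene coordinates were taken from an annotation of the same build.

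Barcodes with at least 500 UMIs, at least 300 genes and under 20% mitochondrial UMIs were kept. These filters removed 154 and 858 of the 5720 NPp53 barcodes for genes and mitochondrial share (some for both), which left 4799, and 220 and 817 of the 4582 NPp53T barcodes, which left 3744. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 0 and 3 barcodes, under the minimum of 0.5%, so the highest scores up to 0.8% per 1000 barcodes were removed instead, 184 in NPp53 and 112 in NPp53T. The remaining 4615 and 3632 barcodes were clustered together with the Leiden method at resolution 1 on 2000 variable genes, 30 components and 15 neighbours, which gave 23 clusters.

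Clusters were named from marker lists of 20 cell types. A name needed at least 3 markers among a cluster's 50 leading genes and no greater number of markers of another type among its 10 leading genes, both read in the round that gave the name. The names are rebuilt here and can differ from those of the study. A first naming scheme set epithelial clusters against all cells only. After the leading genes of the clusters were seen, a round was added that sets them against cells outside the epithelial lineage. In that round a cluster stayed unnamed where more than 1 marker of another type, and more than of its own, stood among its 10 leading genes against all cells. It also stayed unnamed where it was shallow for its library and had no marker of its own type among those 10. The former rule set aside a cluster of 34 cells (33 from NPp53) and the latter a cluster of 590, which would otherwise have been named luminal. Clusters with a median UMI count under 600, or under 1.2 times the floor of 500, were set aside as near-floor. Both steps were fixed after cluster genes and UMI counts were seen and before any comparison of the groups. Of the 23 clusters, 8 were named luminal. With 1 library per group, a cluster mostly of 1 library can reflect that library rather than a cell type.

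UMIs were summed per library and class and given as CPM, the UMIs of a gene per 1000000 UMIs of that class. Sums carry exact Poisson intervals, ratios of sums exact conditional binomial intervals and shares exact Clopper-Pearson intervals, all at 95% and all covering counting error only. With 1 library per group there is no replicate check, and no test between groups was run. Against a library at 0 UMIs, a fold was computed against a floor of 3 UMIs over the class. Genes with at least 20 UMIs over both libraries were measured. A list member counted as higher or lower when its ratio was at least 1.5 in either direction and its interval excluded 1. For each list, the median log2 ratio (NPp53T over NPp53) was set against 10000 random lists of the same size matched on mean expression in 40 bins, and its percentile describes these libraries. A list was said to stand apart when its median was at least 1.5-fold in either direction and its percentile lay outside 2.5 to 97.5. The counting interval of a list's median came from 2000 Poisson draws.

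Named genes followed a rule. Genes needed at least 20 CPM in the higher library and at least 20 UMIs in all. In the higher library they also needed at least 0.2 times their highest CPM in any other named class of that library. The last step was meant to leave out free RNA from other cells. Whether it removed all of it was not tested, and the luminal markers Ltf and Ppp1r1b still passed in fibroblast-like cells. They were ranked by the log2 ratio of CPM plus 5, leaving out mitochondrial, ribosomal protein, haemoglobin and immunoglobulin genes and unnamed gene models. The rule took 12 genes per direction in luminal-like cells and 5 per direction in other classes with at least 50 cells in both libraries, and up to 4 members per list. The target genes Trim28, Pten, Trp53, Nkx3-1 and EYFP were always named. The 28 lists covered proximal luminal, distal luminal secretory, androgen response, NF-kB and acute inflammation, interferon response, MHC class I presentation, MHC class II presentation, apoptosis, p53 targets, integrated stress response, hypoxia and glycolysis, S phase, G2 and M phase, imprinted genes, KRAB zinc finger genes, germline and 2-cell stage genes, epithelial-mesenchymal transition, neuroendocrine lineage, basal and squamous keratins, immediate early and heat shock, and mitochondrially encoded genes. They also covered inflammatory, resident, and lipid-associated macrophage, T cell effector, neutrophil activation, and matrix and inflammatory fibroblast genes. Mx1, Mx2, Cxcl11 and Zfp935 had no entry in the feature table, and Nespas, Ctgf and Cyr61 were matched as Gnasas1, Ccn2 and Ccn1. The groups, marker lists, gene lists, rules for named genes and the alternatives, except those named as added, were fixed before the data were examined.

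Shares of cells with an EYFP UMI were taken after each cell was thinned to 2000 UMIs, leaving out shallower cells, with the unthinned share beside it. After the distribution of EYFP per cell was seen, cells of at least 2000 UMIs were also split at 1200 CPM of EYFP into EYFP-high and EYFP-low. This is a line through a range of values, not a cell type, and luminal-like cells between 800 and 1800 CPM are counted as lying near it.

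The alternatives were other filters (at least 1000 genes, under 10% mitochondrial UMIs, no filter, doublets kept), other clusterings (resolution 0.5 and 2, each library on its own, without the proximal and distal list genes), TMM factors from edgeR 4.0.16, median-of-ratios size factors as in DESeq2 1.42.0, thinned cells, equal weight per cell, totals without mitochondrial and ribosomal protein genes, cells with an EYFP UMI, and other count minimums and pseudocounts. Further ones were added after the data were seen. The 2 scalings moved the median over genes in luminal-like cells by 0.12 in log2, and size factors moved it by 0.10 in basal-like cells. They moved it by less in the other classes.

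The steps that produce ratios, intervals and list percentiles were tested on simulated luminal-like sums, in which 200 genes were drawn to be changed. The results cover 15134 genes, which did not include all of the 200. The interval held the true ratio for 95.4% of genes, and 0.884% of the 14939 unchanged genes were called. The counts were Poisson draws without variation between cells or mice, which is the model behind the intervals. These values therefore check the computation and give no rate of false calls for the real libraries. Calls in the right direction were made for 27.5% of genes at 1.5-fold, 97.5% at 2-fold and 100% at 4-fold higher, and for 94.9% at a ratio of 0.5 and 100% at 0.25. Of 100 lists of unchanged genes, 4 fell outside percentiles 2.5 to 97.5. Analyses used Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3.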

Results

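Whole-prostate cells from 1 NPp53 mouse, made for deletion of Pten and Trp53 in the Nkx3-1 lineage, and 1 NPp53T mouse, made for deletion of Trim28 as well, were profiled by droplet single-cell RNA-seq. The comparison asks what the additional loss of Trim28 does to the cells of these prostates. TRIM28 is a transcriptional corepressor that KRAB zinc finger proteins bring to chromatin. The NPp53 library held 48243045 UMIs in 5720 barcodes, with a median of 640.5 UMIs and 391 genes per barcode. The NPp53T library held 72117073 UMIs in 4582 barcodes, with medians of 7374 UMIs and 2263.5 genes. UMIs were found for 21907 genes in NPp53 and 22652 genes in NPp53T. After filtering, 4615 NPp53 and 3632 NPp53T barcodes remained. Each group had 1 library, so no difference below has a replicate check, and every interval covers counting error only.

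Trim28 (ENSMUSG00000005566, mm10 chromosome 7, 12999114 to 13031035) was lower in the epithelium of the NPp53T library and in its dendritic-like cells, and its ratios in macrophage-like and fibroblast-like cells lay near 1. In luminal-like cells it had 1903 UMIs in NPp53 and 1115 in NPp53T, or 56.6 CPM (95% interval 54.1 to 59.2) and 20.4 CPM (19.2 to 21.6), which is 2.78-fold lower. In luminal-like cells with high EYFP the level was 60.7 CPM in NPp53 and 7.68 CPM in NPp53T, a ratio of 0.127 (0.110 to 0.145). In luminal-like cells with low EYFP it was 39.5 and 37.4 CPM, a ratio of 0.948 (0.822 to 1.10). Basal-like cells had the same contrast, with ratios of 0.157 among EYFP-high and 0.987 among EYFP-low cells (0.504 to 2.11). Trim28 ratios were 0.901 (0.677 to 1.21) in macrophage-like, 1.05 (0.677 to 1.67) in fibroblast-like and 0.607 (0.348 to 1.06) in T or NK-like cells. In dendritic-like cells the ratio was 0.441 (0.227 to 0.835), from 28 and 17 UMIs.

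Pten and Trp53 were targeted in both mice, and their 3' tags did not separate the libraries in luminal-like cells. Pten stood at 81.6 CPM in NPp53 and 79.1 in NPp53T, and Trp53 at 27.1 and 28.5. Within the NPp53 library they were not lower in EYFP-high than in EYFP-low luminal-like cells by over 1.5-fold, at 83.6 and 73.1 CPM for Pten and 26.7 and 29.0 for Trp53. In basal-like cells Pten was 1.76-fold lower in NPp53T, at 159 and 89.9 CPM. The labels do not name the deleted exons, and a 3' tag outside the deleted part checks nothing. Nkx3-1, the homeobox gene whose locus carries the Cre, was 3.24-fold higher (2.88 to 3.66) in NPp53T luminal-like cells, at 9.76 and 31.7 CPM. Among EYFP-high cells it was 6.02-fold higher (4.96 to 7.38), at 4.29 and 25.8 CPM, and among EYFP-low cells the ratio was 1.17 (1.01 to 1.37). Within luminal clusters, Nkx3-1 was higher in those led by Sprr2a3 and Lypd8 (5.74-fold, 3.20 to 10.1), by 9530053A07Rik and Tgm4 (2.29-fold, 1.85 to 2.86) and by Calcb and Clca1 (2.94-fold, 1.08 to 9.25), and in the proliferating cluster (3.46-fold, 1.85 to 7.18). Its ratio was 0.748 (0.616 to 0.912) in the cluster led by Spink1 and Sbp and 0.509 (0.356 to 0.751) in the one led by Stfa1, Cstdc5 and Bglap3, which had 10 NPp53 cells. In the Sprr2a3 and Lypd8 cluster, 94.3% of NPp53 but 25.9% of NPp53T cells were EYFP-high. In the 9530053A07Rik and Tgm4 cluster the shares were 31.4% and 7.72% of cells with at least 2000 UMIs. The Nkx3-1 ratios of these clusters thus also set cells of unlike EYFP level against each other.

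**Figure D1:**
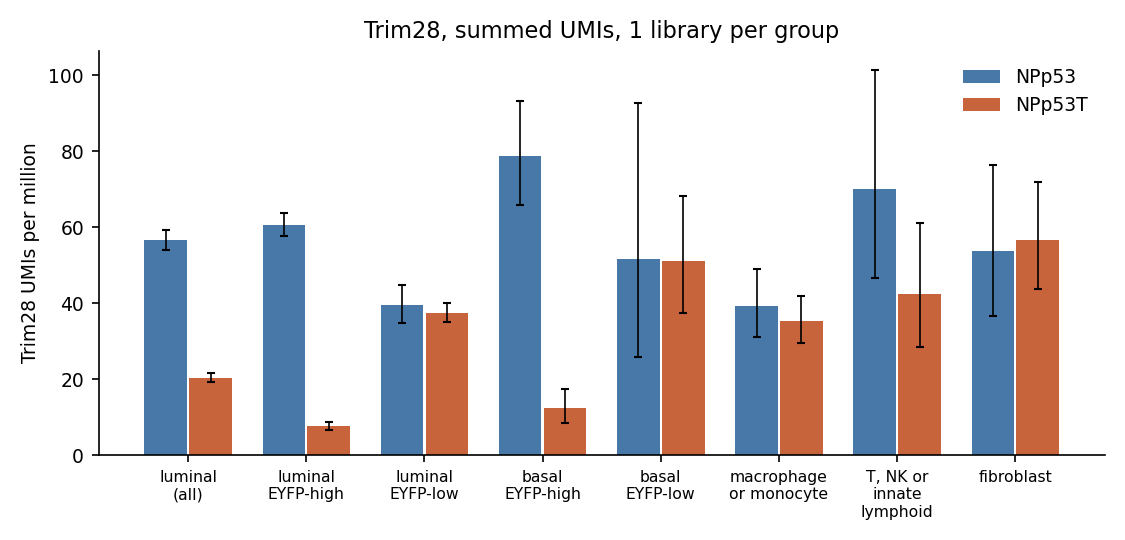
Trim28 level (CPM, y axis from 0) in 8 cell populations of each library; bars are summed UMIs, whiskers the 95% Poisson interval of the counts. In luminal-like cells the level was 60.7 in NPp53 and 7.68 in NPp53T where EYFP was high, and 39.5 and 37.4 where it was low.

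The EYFP lineage mark was found in fewer luminal-like cells of the NPp53T library. After thinning to 2000 UMIs, 776 of 868 NPp53 luminal-like cells (89.4%, 87.2 to 91.4) and 1248 of 1708 NPp53T cells (73.1%, 70.9 to 75.2) had an EYFP UMI, with 55 and 263 shallower cells left out. Unthinned shares were 98.7% and 95.6%. Immune-like cells, which should lack the mark, gave 49.5% (43.6 to 55.3) and 44.1% (40.2 to 48) after thinning, with 65 and 147 cells left out, and 87.5% and 79.7% unthinned. Median depths were 34196 and 25172 UMIs in luminal-like and 7323.5 and 6277 in immune-like cells. Summed EYFP stood at 3733 and 2598 CPM in luminal-like and 373 and 272 CPM in immune-like cells. EYFP per cell was bimodal in luminal-like cells, and a line at 1200 CPM, set after the distribution was seen, split them. Above it lay 696 of 868 NPp53 cells (80.2%, 77.4 to 82.8) and 925 of 1708 NPp53T cells (54.2%, 51.8 to 56.5), against 4.75% and 1.87% of immune-like cells. Between 800 and 1800 CPM lay 31 NPp53 cells (3.57%) and 125 NPp53T cells (7.32%). Basal-like cells above the line made up 81.5% in NPp53 and 65.6% in NPp53T.

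**Figure D2:**
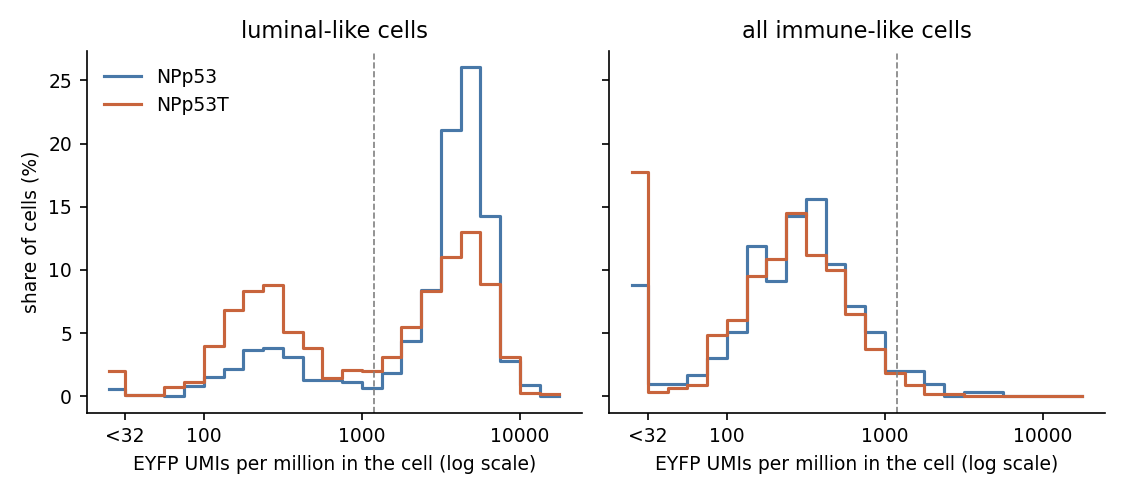
Distribution of EYFP per cell (CPM of the cell, log axis) as the share of luminal-like (left) and immune-like (right) cells of each library with at least 2000 UMIs; the dashed line marks 1200 CPM. Luminal-like cells form a pair of peaks, with 80.2% of NPp53 and 54.2% of NPp53T cells above the line.

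Luminal-like cells were the most frequent named class in both libraries and made up nearly equal shares of the named cells. They were 923 of 1505 named NPp53 cells (61.3%, 58.8 to 63.8) and 1971 of 3207 named NPp53T cells (61.5%, 59.7 to 63.1). Immune-like cells were 23.9% (21.8 to 26.2) and 24.6% (23.1 to 26.1), with macrophage or monocyte-like cells at 15.1% and 15.7%. Basal-like cells were 7.44% and 8.39%, fibroblast-like 4.58% and 4.83%, T or NK-like 3.39% and 3.96%, dendritic-like 2.33% and 2.28%, and B-like cells 0.930% and 1.65%. Neutrophil-like cells were a smaller share in NPp53T, 0.998% (0.683 to 1.41) against 2.19% (1.51 to 3.07), but not of all retained barcodes, where they were 0.881% (0.603 to 1.24) against 0.715% (0.493 to 1.00). Seminal vesicle-like cells, from a neighbouring gland, were 0.499% (0.285 to 0.809) against 2.72% (1.96 to 3.68). Endothelial-like cells numbered 7 in NPp53T and 0 in NPp53. A floor of 3 cells allows up to 0.0650% of the 4615 retained NPp53 barcodes, and the Clopper-Pearson interval ends at 0.0799% of them and at 0.245% of the 1505 named cells.

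The denominator decided the comparison of shares. Of all retained barcodes, luminal-like cells made up 20.0% (18.9 to 21.2) in NPp53 and 54.3% (52.6 to 55.9) in NPp53T, and immune-like cells 7.80% (7.04 to 8.61) and 21.7% (20.4 to 23.1). The gap came with clusters near the UMI floor, which were kept out of all classes by a threshold set after the data were seen. They held 2876 NPp53 barcodes (62.3%, median 535 UMIs) and 35 NPp53T barcodes (0.964%, median 904 UMIs). A further 5.07% and 10.7% were in unnamed clusters. Named cells were deeper in NPp53, with a median of 24174 UMIs against 13739.

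**Figure D3:**
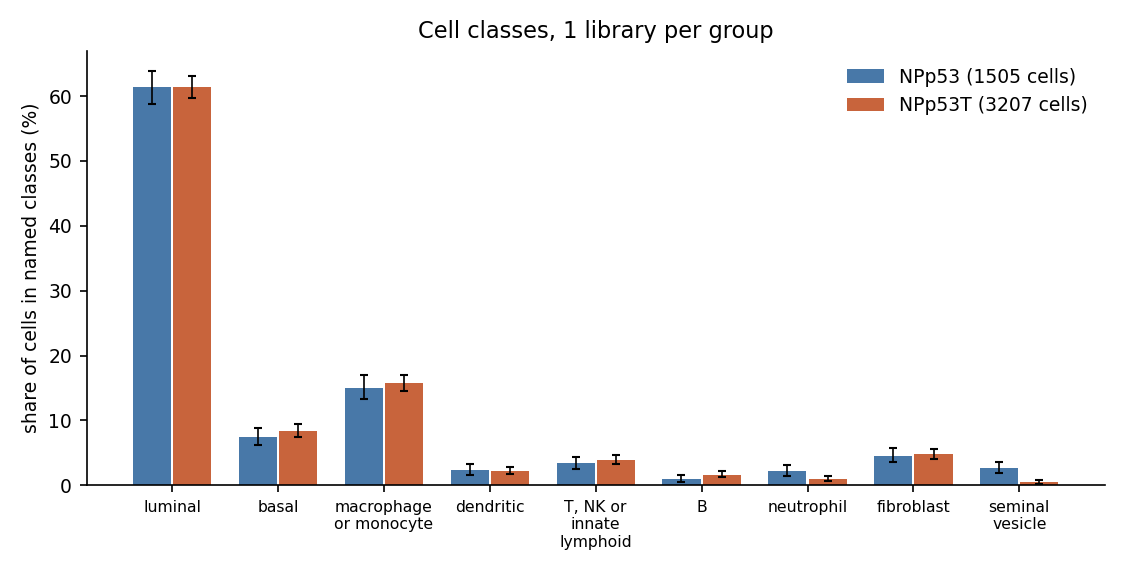
Share of each cell class among cells in named classes (percent, y axis from 0) in each library, with 95% Clopper-Pearson intervals as whiskers; near-floor and unnamed barcodes are left out. Luminal-like cells made up 61.3% in NPp53 and 61.5% in NPp53T.

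Luminal-like cells of the NPp53T library had lower levels of proximal luminal genes and higher levels of distal secretory genes. Proximal luminal cells lie near the urethra and carry a stem-like marker set, while distal cells produce the secretions of the gland. Of 12 proximal genes, 8 were lower, 0 higher and 4 other, with a median log2 ratio of −0.99 (upper interval end −0.97), below all 10000 random lists. Krt4 was 5.68-fold lower (407 and 71.6 CPM), Wfdc2 4.02-fold (2875 and 716 CPM), Psca 3.27-fold (465 and 142 CPM) and Krt7 2.62-fold lower (282 and 108 CPM). Of 20 distal genes, 17 were higher, 0 lower and 3 other, with a median of 1.30 (1.28 to 1.33), above all random lists. Spink8 was 13-fold higher (6.78 and 88.5 CPM), 9530053A07Rik 7.32-fold (39.7 and 290 CPM), the transglutaminase gene Tgm4 5.79-fold (45.6 and 264 CPM) and probasin, Pbsn, 4.02-fold higher (143 and 573 CPM).

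Both lists kept these directions among EYFP-high luminal-like cells, where the proximal median was −0.95 with 7 of 12 genes lower and the distal median 1.79 with 18 of 20 higher. Among EYFP-low cells the medians were 0.12 for both lists. Different clusters held most of the luminal-like class in each library. In NPp53 these were led by Sprr2a3, Lypd8 and Gsdmc3 and by Calcb and Clca1. In NPp53T they were led by Stfa1, Cstdc5 and Bglap3, by Spink1 and Sbp, by 9530053A07Rik and Tgm4, and, at low depth, by Cstdc5 and Bglap3. Of the NPp53T cells with at least 2000 UMIs in these clusters, in that order, 95.5%, 23.2%, 7.72% and 57.3% were EYFP-high. The NPp53 clusters just named were 94.3% and 95.4% EYFP-high in NPp53, and 25.9% and 78.4% in NPp53T. Whole-class ratios of genes leading the Spink1 and Sbp or the 9530053A07Rik and Tgm4 cluster thus weigh many EYFP-low cells. With equal weight for each luminal cluster found in both libraries, an alternative added after the data were seen, the proximal median was −0.31 and the distal median 0.29. That weighting gives clusters of mostly EYFP-low NPp53T cells the same weight as the others. In the Calcb and Clca1 cluster, well filled in both libraries, the proximal median was −0.19 and the distal median 1.06. That cluster had a urothelial and no luminal marker among its 10 leading genes against all cells, and was named luminal only against cells outside the epithelial lineage. Without it, an alternative added after the data were seen, the medians of the class were −1.04 and 1.09.

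Keratin and squamous genes were also lower in NPp53T luminal-like cells, and androgen response genes as a list stayed near the level of other genes. Of 16 basal and squamous genes, 11 were lower and 0 higher, with a median of −1.07 (−1.15 to −0.85), below all random lists. Examples were Krt15, 3.38-fold lower (1754 and 520 CPM), the desmosomal cadherin Dsg3, 4.97-fold (14.9 and 3.00 CPM), and the stress keratins Krt16, 2.5-fold, and Krt6a, 2.31-fold lower. The keratin median was −0.50 without a filter on low counts and −0.54 with equal weight per cluster, both under 1.5-fold. In EYFP-low cells the same list ran the other way, with a median of 1.75 (1.38 to 2.15) and 11 genes higher, among them Sprr1a (9.23-fold, 16.6 and 153 CPM), Lgals7 (8.82-fold) and Krt17 (4.12-fold). The androgen response list had a median of −0.23, at percentile 6.88, with 2 genes higher, 7 lower and 16 other. Its split was 4 higher and 6 lower with TMM factors. Azgp1 was 2.76-fold higher (141 and 389 CPM) and Aldh1a3, a retinaldehyde dehydrogenase gene, 4.11-fold lower (113 and 27.4 CPM).

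Neuroendocrine and mesenchymal genes did not stand apart as lists. Of 6 measured neuroendocrine genes, 2 were higher and 2 lower, with a median of −0.11 at percentile 45.6, and −0.95 after thinning to 2000 UMIs per cell. Chga, which encodes chromogranin A, was 19.9-fold lower (11.1 to 39.4, 4.37 and 0.220 CPM), Sox2 1.73-fold lower, and Calca 5.64-fold higher (0.179 and 1.01 CPM). Of 16 epithelial-mesenchymal transition genes, 3 were higher, 2 lower and 11 other (median −0.09, percentile 52.7). Zeb2 was 4.32-fold higher (1.28 and 5.53 CPM), and Inhba 3.43-fold and Mmp14 2.16-fold lower.

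**Figure D4:**
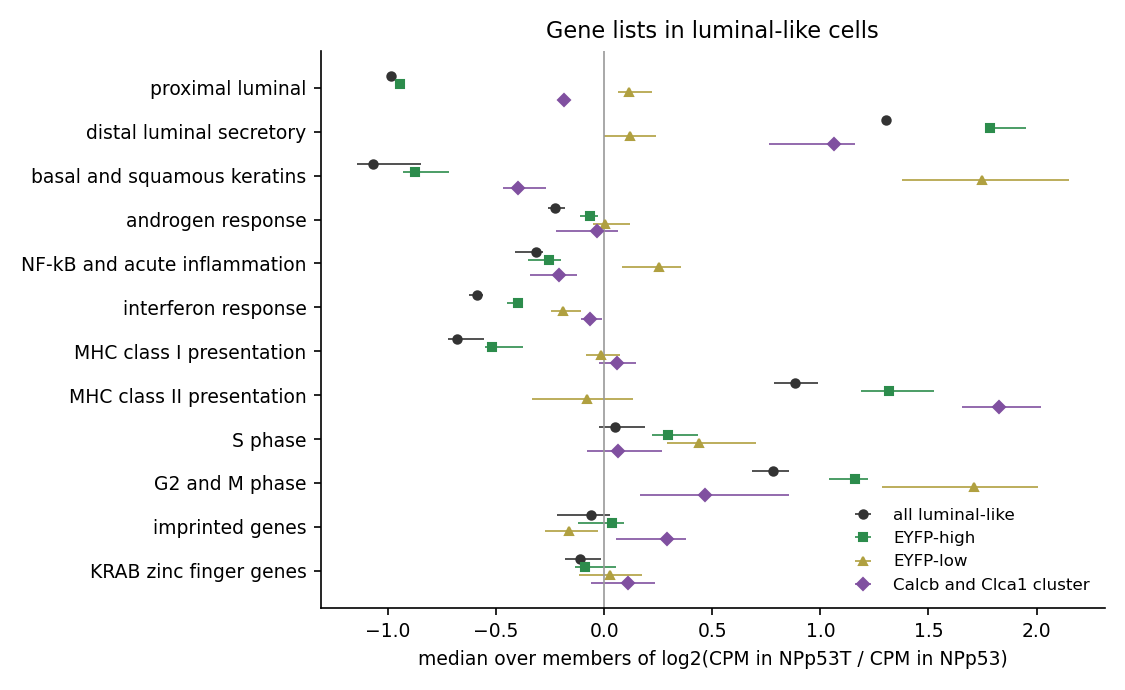
Median over members of the log2 ratio of CPM (NPp53T over NPp53, x axis) for 12 gene lists in all luminal-like cells, EYFP-high cells, EYFP-low cells and the cluster led by Calcb and Clca1; whiskers are counting intervals. The proximal median was −0.99 in all luminal-like cells, −0.95 in EYFP-high and 0.12 in EYFP-low cells, and the distal median 1.30, 1.79 and 0.12.

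Interferon and MHC class I genes were lower, and MHC class II genes higher, in luminal-like cells of the NPp53T library. Of 42 interferon response genes, 22 were lower, 0 higher and 20 other, with a median of −0.59 (−0.63 to −0.56), below all random lists. Cmpk2 was 3.05-fold lower (77.5 and 25.4 CPM), Ifit3b 3.04-fold (78.6 and 25.9 CPM), Oasl1 2.69-fold (123 and 45.7 CPM) and Ifit3 2.37-fold lower (270 and 114 CPM). Of 14 class I presentation genes, 8 were lower and 0 higher (median −0.68, −0.72 to −0.56), with H2-T23 2.17-fold (295 and 136 CPM) and H2-Q7 1.90-fold lower. With TMM factors 15 interferon genes were lower (median −0.47) and 5 class I genes (median −0.56), and neither list stood apart. Of 7 class II presentation genes, 6 were higher and 0 lower, with a median of 0.88 (0.79 to 0.99) at percentile 99.99. Cd74, the invariant chain gene, was 1.92-fold higher (49.4 and 94.7 CPM), H2-Ab1 1.84-fold, H2-Aa 1.81-fold and H2-DMb1 2.49-fold higher.

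The interferon median was −0.40 among EYFP-high cells (12 of 42 lower), −0.19 among EYFP-low cells and −0.12 with equal weight per cluster. Class I medians were −0.52 and −0.02 in EYFP-high and EYFP-low cells, and −0.48 with equal weight per cell. Class II genes had a median of 1.32 in EYFP-high cells, with Cd74 2.84-fold higher (45.1 and 128 CPM), and −0.08 in EYFP-low cells, while the class II median in immune-like cells was −0.11. In the Calcb and Clca1 cluster all 6 measured class II genes were higher (median 1.82) and the interferon median was −0.07. When each library was clustered on its own, the class II median turned to −1.37, and when clusters were built without the luminal lists it was 0.52.

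NF-kB and acute inflammation genes leaned lower without standing apart. Of 36 genes, 14 were lower, 3 higher and 19 other, with a median of −0.32 (−0.41 to −0.28) at percentile 0.25. Neutrophil-attracting chemokine genes led them, with Cxcl5 7.90-fold lower (6.95 to 8.99, 42.0 and 5.32 CPM) and Cxcl3 6.98-fold (10.1 and 1.45 CPM). The acute-phase genes Saa3 and Saa1 were 4.49-fold (13.1 and 2.91 CPM) and 2.58-fold lower. The median was −0.25 among EYFP-high cells, 0.25 among EYFP-low cells and −0.12 with equal weight per cluster.

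Mitotic genes were higher in NPp53T luminal-like cells, while death and stress genes were mostly within 1.5-fold. Of 26 genes of G2 and M phase, 17 were higher, 0 lower and 9 other (median 0.78, 0.68 to 0.85), above all random lists. Cenpa was 3.19-fold higher (6.49 and 20.7 CPM), Cdc20 2.84-fold (4.08 and 11.6 CPM), Ube2c 2.55-fold (11.4 and 29.1 CPM) and Anln 2.19-fold higher. The G2 and M median was 1.16 in EYFP-high and 1.71 in EYFP-low cells. It was under 1.5-fold with each library clustered on its own (0.52), with equal weight per cell (0.53), without a filter on low counts (0.53) and with equal weight per cluster (0.32). S phase genes had a median of 0.05, with 2 of 25 higher, Dtl among them (1.65-fold). Of 23 apoptosis genes, 6 were lower and 0 higher (median −0.23, percentile 9.88), with the BH3-only gene Pmaip1 3.26-fold (239 and 73.5 CPM) and Casp3 1.74-fold lower. Of 20 p53 targets, 2 were higher and 2 lower (median 0.07, percentile 99.3), and 4 higher and 2 lower with TMM factors. Gdf15 was 2.28-fold and Plk2 1.77-fold lower, and Ckap2 2.76-fold higher.

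The integrated stress response list had a median of −0.11 (percentile 59.2) with 1 of 18 genes higher, Psat1 (1.5-fold). Hypoxia and glycolysis genes had a median of −0.22 (percentile 7.34) with 4 of 24 lower, including Egln3 (1.99-fold) and Vegfa (1.78-fold). Of 24 immediate early and heat shock genes, which also follow tissue handling, 2 were lower, Hspa1a 1.65-fold (1423 and 865 CPM) and Dnajb1 1.54-fold (median −0.28, percentile 0.45). Mitochondrially encoded genes had a median of −0.42, with 0 of 13 higher or lower. The median over all 15140 genes measured in luminal-like cells was −0.12, and other scalings moved it by 0.12, so list medians within that distance of 0 have no firm direction.

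Gene groups tied to TRIM28 function moved little as lists in the whole luminal-like class. Of its NPp53T cells with at least 2000 UMIs, 54.2% were EYFP-high, and the Trim28 ratio in EYFP-low cells was 0.948. The class values below thus weigh many cells that kept Trim28, and can understate a change in the cells that lost it. Of 58 measured KRAB zinc finger genes, whose proteins recruit TRIM28, 3 were higher, 7 lower and 48 other (median −0.11, percentile 55.5), and 6 higher and 5 lower with TMM factors. Zfp791 was 4.23-fold higher (5.18 and 21.9 CPM), and 7.28-fold among EYFP-high cells (4.55 and 33.1 CPM). Zfp52 was 1.87-fold higher and Zfp458 2.06-fold lower. Of 24 imprinted genes, 2 were higher and 6 lower (median −0.06, percentile 58.2), or 4 higher and 5 lower with TMM factors. Snrpn was 1.5-fold higher and Nnat, which encodes neuronatin, 6.44-fold lower (12.5 and 1.94 CPM). Of the 30 germline and 2-cell stage genes only 5 were measured (median −0.16, percentile 44.5, and −1.39 after thinning), with Piwil2 2.49-fold higher (0.655 and 1.63 CPM) and Dazl 2.80-fold lower (1.64 and 0.586 CPM).

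Markers of other cell types were read in the same luminal-like sums, where free RNA contributes. The inflammatory macrophage list had a median of −0.77 there with 11 of 20 genes lower, and the neutrophil activation list −0.65 with 9 of 18 lower. T cell effector genes had a median of −0.48, resident macrophage genes 0.24, lipid-associated macrophage genes 0.11 and inflammatory fibroblast genes 0.27. Matrix fibroblast genes had a median of 0.84, with 9 of 16 higher. Conversely, macrophage-like cells carried luminal genes with the sign of their library, with medians of −1.21 for the proximal and 1.00 for the distal list. The macrophage-like class includes a cluster of 64 NPp53 and 121 NPp53T cells with a median of 920 UMIs and more epithelial RNA than its other clusters. Without it the medians were −0.69 and 1.42.

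Among the genes named by rule in luminal-like cells, Stfa1 and Bglap3 had the largest ratios on the higher side and Muc19 and Sprr2a3 on the lower side. Bglap3, an osteocalcin-family gene (ENSMUSG00000074489, mm10 chromosome 3, 88368616 to 88372743), had 101 UMIs in NPp53 and 31766 in NPp53T, or 3.01 and 581 CPM, which is 193-fold higher (159 to 238). Stfa1, a stefin gene (ENSMUSG00000071562, chromosome 16, 36276951 to 36285373), had 1 UMI in NPp53 and 6895 in NPp53T, a ratio of 4240 with an interval of 761 to 1.675e+05. Its log2 ratio of 12.05 was 6.19 after thinning to 2000 UMIs per cell. Lix1 (ENSMUSG00000047786, chromosome 17, 17402672 to 17459387) was 23.3-fold higher (19.1 to 28.8, 2.92 and 68.1 CPM). The other genes named as higher were Scgb1b27 (33.3-fold), Scgb2b27 (29.4-fold), Mug1 (17-fold), Cstdc5 (13-fold), Ly6k (11.8-fold), Prr9 (10.5-fold) and Bcl2l15 (5.45-fold), with Spink8 and Tgm4 as above. With equal weight per cell the log2 ratio of Tgm4 went from 2.53 to 1.32 and that of Spink8 from 3.71 to 2.83. For Scgb1b27, 1 cell supplied 45.4% of the NPp53T UMIs and 1 cell 79.5% of the NPp53 UMIs.

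At the other end, Sprr2a3, a small proline-rich protein gene (ENSMUSG00000074445, chromosome 3, 92285417 to 92291405), had 24335 UMIs in NPp53 and 707 in NPp53T, or 724 and 12.9 CPM, which is 56.0-fold lower (51.9 to 60.4). The mucosal peptide gene Tff3 (ENSMUSG00000024029, chromosome 17, 31125306 to 31129646) was 7.77-fold lower (7.62 to 7.93, 1599 and 206 CPM). The mucin gene Muc19 was 112-fold lower, Lypd8 51.8-fold, Crym 20.9-fold, Fcgbp 13.9-fold and Sval1 8.75-fold lower. The gasdermin genes Gsdmc2, Gsdmc3 and Gsdmc4 were 15.6-fold, 16.0-fold and 16.9-fold lower. Klk1 was 16.5-fold and Obp2a 16.0-fold lower, with 95.4% of the NPp53T UMIs of Klk1 and 61.4% of the NPp53 UMIs of Obp2a from 1 cell each. All of these 24 genes except Ly6k and Muc19 were also among the 10 leading genes, against all other cells, of luminal clusters with most of their cells from 1 library. Obp2a was lower in NPp53T although its cluster, led by 9530053A07Rik and Tgm4, had 89 NPp53 and 337 NPp53T cells. Muc19 was among the 10 leading genes of the cluster led by Sval1 and Tff3 against cells outside the epithelial lineage.

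Among EYFP-high luminal-like cells, the same rule took 21 of the same 24 genes. Bglap3 was 264-fold higher (3.56 and 938 CPM) and Sprr2a3 63.7-fold lower (884 and 13.9 CPM). Gstm1, a glutathione transferase gene, was 7.29-fold higher (33.4 and 243 CPM), Krt4 8.04-fold lower (477 and 59.3 CPM) and the tetraspanin gene Tspan8 6.58-fold lower (1072 and 163 CPM).

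**Figure D5:**
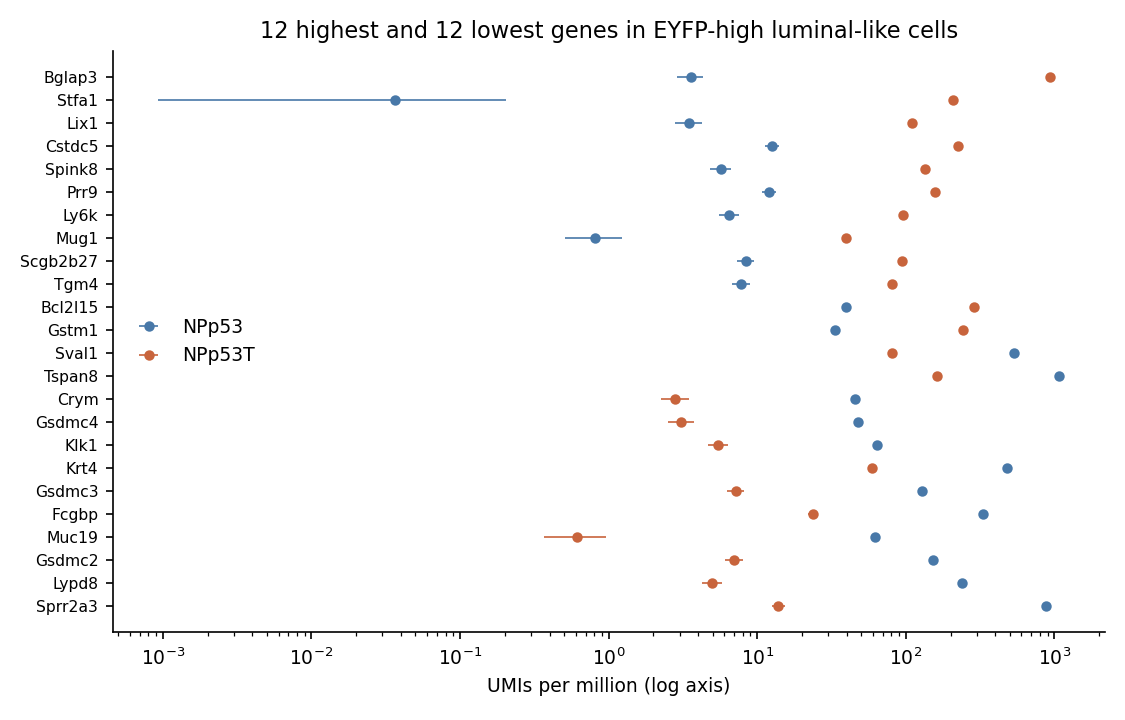
CPM (log axis) of the 12 highest and 12 lowest genes by rule in EYFP-high luminal-like cells of each library; points are summed UMIs and whiskers 95% Poisson intervals. Bglap3 lay at 3.56 in NPp53 and 938 in NPp53T, and Sprr2a3 at 884 and 13.9.

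In basal-like cells (112 in NPp53 and 269 in NPp53T), distal secretory and MHC class II genes were higher in the NPp53T library. The distal list was also higher in classes outside the epithelium, where free luminal RNA is read, with medians of 1.00 in macrophage-like and 1.92 in fibroblast-like cells. Of 15 measured distal genes, 12 were higher and 0 lower (median 1.51, above all random lists), with Azgp1 9.07-fold (4.68 and 42.5 CPM), Defb50 4.61-fold and Spink1 3.87-fold higher. Of 5 class II genes, 4 were higher (median 1.66), with Cd74 2.54-fold higher (17.2 and 43.6 CPM), and 4 of 11 genes of G2 and M phase were higher (median 0.82). With barcodes limited to under 10% mitochondrial UMIs, the distal median turned to −0.49, the class II median was 0.092 and the G2 and M median 0.46. The G2 and M median was 0.37 after thinning and 0.21 over members with at least 200 UMIs. Proximal genes had a median of −0.37 with 5 of 12 lower.

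NF-kB genes did not stand apart in basal-like cells. Of 22 measured, 5 were higher, 2 lower and 15 other, with a median of 0.33, under 1.5-fold, which was 0.10 with each library clustered on its own and 0.00047 at resolution 2. The leukaemia inhibitory factor gene Lif was 3.48-fold (25.0 and 87.0 CPM), Il6 4.66-fold (3.12 and 14.5 CPM) and Cxcl2 2.53-fold higher, while C3 was 3.08-fold lower. Interferon genes went both ways, with 13 of 42 lower, 5 higher and a median of −0.47. Ifit3 was 2.60-fold lower, whereas Cxcl10 was 3.48-fold (89.5 and 312 CPM) and Cxcl9 15.2-fold higher, with 53.9% of the NPp53T Cxcl9 UMIs from 1 cell and a Cxcl9 log2 ratio that went from 3.92 to 2.37 after thinning. Keratin genes had a median of −0.01, with Krt13 12.1-fold lower (127 and 10.5 CPM) and Ly6d 2.35-fold higher. Class I genes had a median of −0.12, with 2 of 13 lower and 0 higher, or 2 lower and 1 higher with TMM factors. Immediate early and heat shock genes had 5 of 24 lower and 0 higher, or 3 lower and 1 higher with TMM factors.

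Genes named in basal-like cells overlapped those of luminal-like cells. Bcl2l15 had 3 UMIs in NPp53 and 172 in NPp53T (ratio 32.1, 10.8 to 157), Lix1 3 and 143 (ratio 26.7, 8.94 to 131) and Ly6k 4 and 155 (ratio 21.7, 8.30 to 80.5). After thinning to 2000 UMIs per cell, the log2 ratios of Bcl2l15, Lix1 and Ly6k were 2.96, 3.37 and 1.85. Mbd1, a methyl-CpG-binding protein gene, was 6.84-fold higher (5.35 to 8.88). Lower were the serpin gene Serpinb2, 116-fold (52.8 to 318, 202 and 1.75 CPM), Gsdmc2, 73.0-fold (212 and 2.91 CPM, with 80.0% of the NPp53T UMIs from 1 cell), Psca, 14.4-fold (188 and 13.1 CPM), and Sprr2a3, 9.42-fold. After thinning, the log2 ratio of Serpinb2 went from −6.86 to −4.21 and that of Psca from −3.85 to −2.38.

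Macrophage or monocyte-like cells (227 in NPp53 and 504 in NPp53T) had no list of macrophage genes that stood apart. Of 18 resident macrophage genes, 7 were higher, 0 lower and 11 other, with a median of 0.40 (0.29 to 0.50), above all random lists but under 1.5-fold. The class mixes clusters in different proportions, since the one led by Ccl8, Fcna and Folr2 held 40 of 227 NPp53 cells (17.6%) and 147 of 504 NPp53T cells (29.2%), and the one led by Rgs1, Spp1 and Ctss 54.2% and 46.8%. Within them, in a comparison added after the data were seen, the resident macrophage medians were 0.075 (2 higher and 2 lower of 17) and −0.24 (0 higher and 4 lower of 14), and the inflammatory macrophage medians 0.10 and −0.16. In the remaining cluster of the class, which is of low depth, the resident median was 0.63 (2 higher and 1 lower of 11). The inflammatory median there was −0.89 (0 higher and 4 lower of 8). The resident median of the class was 0.45 with 6 genes higher without the low-depth cluster of the class, an alternative added after the data were seen, and 0.16 after thinning to 2000 UMIs per cell. Cd209f was 6.33-fold higher (40.8 and 258 CPM), the hyaluronan receptor gene Lyve1 3.29-fold (78.1 and 257 CPM), Folr2 2.25-fold (213 and 478 CPM) and Gas6 2.23-fold higher (107 and 239 CPM). Within the Ccl8, Fcna and Folr2 cluster, Cd209f was 2.98-fold and Lyve1 1.59-fold higher, and the Folr2 and Gas6 ratios were both 1.27. Inflammatory macrophage genes had a median of −0.23 (−0.37 to −0.02), at percentile 0.085, with 5 of 21 lower, 1 higher and 15 other, and 5 lower and 2 higher with TMM factors. The interleukin genes Il1b and Il1a were 2.03-fold (1.94 to 2.13, 1792 and 882 CPM) and 2.19-fold lower, with ratios of 0.601 and 0.522 within the Rgs1, Spp1 and Ctss cluster. Inhba was 5.98-fold lower, with 70.1% of its NPp53 UMIs from 1 cell.

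Other macrophage lists had members on both sides. Of 17 lipid-associated and alternative genes, 2 were higher and 2 lower (median 0.01), with Chil3 3.26-fold and Gpnmb 2.39-fold higher, Arg1 2.82-fold lower and Spp1 3.09-fold lower, 53.5% of its NPp53 UMIs from 1 cell. Of 42 interferon genes, 4 were higher and 2 lower (median 0.13), with Iigp1 7.58-fold (17.4 and 132 CPM) and Cxcl9 1.86-fold higher and Cxcl10 2.05-fold lower. The NF-kB median was −0.16, with Ccl7 2.35-fold higher (567 and 1335 CPM), and the class II median −0.14 with no gene called. Named as higher were Tmem267 (12.9-fold), Cd209d (9.51-fold, with 85.7% of its NPp53 UMIs from 1 cell), Cd209f and Iigp1, as above, and Cma1. With 0 UMIs in NPp53 and 127 in NPp53T, Cma1 was 23-fold higher against the floor of 3 UMIs. Cma1, a mast cell protease gene, had 33.9% of its UMIs in 1 cell and turned lower, at a log2 ratio of −1.35, with doublets kept. Named as lower were Arl14 (21.3-fold, 28.8 and 1.35 CPM, with 69.0% of its NPp53 UMIs from 1 cell), Arsb (6.63-fold) and Hist1h1b (2.92-fold).

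T or NK-like cells (51 in NPp53 and 127 in NPp53T) had no list that stood apart. Effector and checkpoint genes had a median of −0.18, with 2 of 16 higher and 3 lower. Lag3, an inhibitory receptor gene, was 3.04-fold lower (40.1 and 13.2 CPM), Il17f 3.98-fold lower and Il17a 3.71-fold higher. Interferon genes had a median of −0.24 with 3 of 35 lower. Of 21 genes of G2 and M phase, 1 was higher and 2 were lower, or 1 lower with TMM factors, and the median of 0.06 was 1.71 with each library clustered on its own. Hopx was 5.29-fold higher (3.57 to 8.12, 70.1 and 371 CPM), Bend4 7.76-fold and Rell1 5.56-fold. Sfi1 had 1 UMI in NPp53 and 19 in NPp53T (ratio 11.1, 1.77 to 462), and Gzmd was 5.78-fold higher with 98.7% of its NPp53T UMIs from 1 cell. After thinning to 2000 UMIs per cell, the log2 ratio of Sfi1 went from 3.48 to 0.15 and that of Gzmd from 2.53 to 0.59. Ifi208 was 8.54-fold and Wdr83os 4.61-fold lower, and Gzme, Ifitm1 and Ntrk3 were 9.0-fold, 6.64-fold and 5.69-fold lower. For Ifi208, Gzme, Ifitm1 and Ntrk3, 1 cell supplied most of the NPp53 UMIs.

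Fibroblast-like cells (69 in NPp53 and 155 in NPp53T) had higher levels of matrix and activation genes in the NPp53T library. Of 21 genes, 12 were higher and 0 lower, with a median of 0.88 (0.66 to 0.96), above all random lists. Tagln, a contractile gene, was 15-fold higher (6.30 to 46.9, 8.67 and 130 CPM; log2 ratio 3.91, and 2.51 with equal weight per cell), the matrix metalloproteinase gene Mmp3 5.93-fold (31.2 and 185 CPM) and Col12a1 3.40-fold higher (57.2 and 194 CPM). Acta2 had 1 UMI in NPp53 and 62 in NPp53T (ratio 30.6, 5.30 to 1229), and its log2 ratio of 4.94 was 0.74 after thinning to 2000 UMIs per cell. Thinning also took the matrix list to a median of 0.54, under 1.5-fold. Inflammatory fibroblast genes had a median of 0.07, with 6 of 19 higher and 1 lower. Saa3 was 5.76-fold, Cxcl14 3.86-fold (118 and 455 CPM) and Ptx3 1.98-fold higher, and Ccl8 3.09-fold lower. The interferon median was −0.08, with 3 of 39 lower and 0 higher, or 3 lower and 1 higher with TMM factors.

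Luminal genes in fibroblast-like cells followed their library, with medians of −1.67 for the proximal and 1.92 for the distal list. Named as higher were Creld2 (7.95-fold, 20.8 and 165 CPM), Pdgfrl with 2 UMIs in NPp53 and 80 in NPp53T (ratio 19.8, 5.30 to 166), and Cdc20 with 0 and 25, at least 4.12-fold higher, 56.0% of them from 1 cell. The log2 ratio of Pdgfrl was 4.30, and 0.48 after thinning. Named as lower were Ltf (46.0-fold, with 94.3% of its NPp53 UMIs from 1 cell), Ppp1r1b with 20 and 1 UMIs (40.5-fold, 6.47 to 1678), Angpt1 (9.44-fold), Tslp (8.96-fold) and Lamc3 (6.07-fold). For Ppp1r1b, Angpt1, Tslp and Lamc3, 1 cell supplied 55.0%, 67.9%, 77.4% and 52.4% of the NPp53 UMIs.

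Neutrophil-like cells were few, 33 in NPp53 and 32 in NPp53T. Of 18 neutrophil activation genes, 5 were higher and 0 lower, with a median of 0.45 (0.30 to 0.60) at percentile 99.8, under 1.5-fold, which turned to −0.28 with at least 1000 genes per barcode. Mmp9, a gelatinase gene, was 2.44-fold and Hilpda 2.08-fold higher. The NF-kB median was 0.01, with 3 of 19 higher and 1 lower, and −0.95 with at least 1000 genes.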

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

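The tests of Trim28 in EYFP-low and EYFP-high cells, of subtracting immune-level RNA from the proximal list and of keratin genes by EYFP level were chosen only after the result was seen, and the others before. Most NPp53 barcodes, 62.3% of those retained against 0.964% in NPp53T, lay in clusters near the UMI floor, outside every class that was compared. A share of 10.7% of NPp53T cells, against 5.07% of NPp53 cells, lay in clusters without a name and was also left out of the comparisons. Basal and squamous keratin genes had a median log2 ratio of −0.88 in EYFP-high and 1.75 in EYFP-low luminal-like cells, opposite directions under the same contrast, and the difference between the subsets was not tested.

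The near-floor barcodes of the NPp53 library may be empty droplets filled with free RNA or shallow cells, which cannot be told apart here. Lower depth of that library as the whole cause is argued against by thinning the NPp53T library to the NPp53 total (keeping 66.9% of UMIs), which gave 4.14% of barcodes under 600 UMIs, against 46.4% in NPp53. Empty droplets should share immune marker UMIs evenly, with a variance close to the mean, and the value of 11.7 passed the limit of 1.5 set beforehand, but its resampled interval of 1.07 to 31.2 spans that limit. A single barcode with 255 such UMIs, 199 of them Ighm and 51 Igkc, made the excess, and without it, a step taken after the result, the value was 1.13. Luminal-like cells alone gave 1.52 when thinned alike, and luminal-like and immune-like cells together 46.5, so the test separates a mix of cell types from empty droplets better than it separates shallow luminal cells.

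Proximal luminal genes were lower in the NPp53T luminal-like class, and a different mix of luminal states in the 2 libraries may account for part of it. Within the 6 luminal clusters with at least 30 cells in both libraries, the median over clusters was −0.27, between −0.94 and 0.06, and −0.32 when clusters were built without the genes of both luminal lists. In NPp53T, 25.9% of the Sprr2a3 and Lypd8, 23.2% of the Spink1 and Sbp and 7.72% of the 9530053A07Rik and Tgm4 cluster were EYFP-high. Their medians were 0.06, 0.0067 and −0.36. The proliferating cluster (86.9%) had −0.94, the low-depth Cstdc5 and Bglap3 cluster (57.3%) −0.69 and the Calcb and Clca1 cluster (78.4%) −0.19. Where most cells were EYFP-low, a value near 0 can arise without a different mix, so the median over clusters does not decide. Clusters filled by 1 library could not enter, and whether the mix follows from the loss of Trim28, the dissection or the mouse was not tested. A larger number of unrecombined cells in NPp53T is argued against as the cause by the EYFP-high cells, which alone had −0.95 (−0.97 to −0.92). The level set beforehand for free RNA as a cause was met, since the list summed to 24447 CPM in NPp53 near-floor barcodes against 19484 in its luminal-like cells, but that level does not show how much free RNA the cells took up, and subtracting each library's immune-like level, a step chosen after that value, left −1.31 (−1.35 to −1.26), which argues against it as the whole cause.

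Part of the NPp53T luminal-like class kept Trim28 UMIs, and cells that did not recombine are a candidate explanation. The NPp53T to NPp53 ratio was 0.948 (0.822 to 1.10) in EYFP-low and 0.127 in EYFP-high luminal-like cells. Free RNA as the whole cause is argued against within the NPp53T library, where droplets should take up like amounts of it. EYFP-low cells there held 1.11 Trim28 UMIs per cell and EYFP-high cells 0.258, a ratio of 4.31 (3.73 to 4.99). A smaller contribution of free RNA stays open.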

How the results depend on the processing

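The alternatives that use EYFP-high or EYFP-low cells, equal weight per cluster, luminal classes without a cluster, named cells as denominator, cells with at least 2000 UMIs, near-floor clusters counted as luminal, the macrophage-like class without its low-depth cluster and the 1200 CPM line were chosen after seeing the data. No paired analysis was possible because each group had 1 library. Of 172 alternative values of the main results, 102 stayed within the counting interval of the reported value, 66 moved beyond it and 4 reversed. Of 1171 values of single genes and further lists, 840 stayed, 326 moved and 5 reversed. Only results that had been called could count as reversed. Other changes of sign, as for the NF-kB median in EYFP-low luminal-like cells, count as moved or stayed. The named genes have no counting interval and were counted as staying by their overlap with the reported set. Unless stated, the cause was not tested. The inflammatory macrophage list kept its median of −0.23 within its interval in every alternative run, and the rule named at least 20 of the same 24 luminal genes in each. Summed UMIs were fewest in the neutrophil-like, T or NK-like and fibroblast-like classes, where few UMIs stand behind each ratio. Basal-like and macrophage-like cells, with sums close to each other, also held far fewer than luminal-like cells.

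The proximal luminal median in luminal-like cells (−0.99) was −0.93 without a filter, −1.02 under 10% mitochondrial UMIs, −0.92 with each library clustered on its own, −0.86 with TMM factors, −0.87 with size factors, −0.83 after thinning and −0.83 with equal weight per cell. It was −0.95 in EYFP-high cells, reversed to 0.12 in EYFP-low cells, and was −0.31 with equal weight per cluster, −1.04 without the Calcb and Clca1 cluster and −0.72 without the Spink1-rich cluster. In the same order, the distal luminal secretory median in luminal-like cells (1.30) was 1.33, 1.09, 1.15 at resolution 2, 1.43 and 1.43 with TMM and size factors, 1.15 after thinning, 1.21 with equal weight per cell and 1.19 without a count filter. It was 1.79 in EYFP-high and 0.12 in EYFP-low cells, 0.29 with equal weight per cluster, and 1.09 and 1.87 without those clusters.

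The NF-kB and acute inflammation median in luminal-like cells (−0.32) was −0.28 with doublets kept, −0.28 at resolution 2, −0.42 with each library on its own, −0.19 with TMM and −0.19 with size factors, −0.48 after thinning and −0.25 without a count filter. It was −0.25 in EYFP-high and 0.25 in EYFP-low cells, −0.12 with equal weight per cluster, −0.17 without the Calcb and Clca1 and −0.18 without the Spink1-rich cluster. The interferon response median in luminal-like cells (−0.59) was −0.53 without a filter, −0.64 under 10% mitochondrial UMIs, −0.69 at resolution 2, −0.47 with TMM and −0.47 with size factors, −0.50 after thinning, −0.45 with equal weight per cell and −0.53 without a count filter. It was −0.40 in EYFP-high and −0.19 in EYFP-low cells, −0.12 with equal weight per cluster, and −0.52 and −0.36 without those clusters. The log2 ratio of Trim28 in luminal-like cells (−1.47) was −1.35 with TMM and −1.35 with size factors, −1.18 after thinning, −1.25 with equal weight per cell, −2.98 in EYFP-high and −0.078 in EYFP-low cells, and −0.90 with equal weight per cluster.

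The share of luminal-like cells, NPp53T minus NPp53, was 34.3 percentage points of retained barcodes. It reversed to −0.818 with at least 1000 genes, to −0.201 with at least 2000 UMIs, and to −27.1 with near-floor clusters counted as luminal. It was 28.2 without a filter, 31.5 when clustered without the luminal lists and 0.130 of named cells. These settings remove or reassign the near-floor barcodes of NPp53. The share of immune-like cells, 13.9 points higher, was 3.68 with at least 1000 genes, 11.4 without a filter, 0.682 of named cells and 3.37 with at least 2000 UMIs. The share of luminal-like cells with an EYFP UMI, at −16.3 points, was −9.01 after thinning to 5000 UMIs, −3.06 without thinning and −26.0 at the 1200 CPM line.

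Other reversals were the MHC class II presentation median in luminal-like cells, −1.37 with each library clustered on its own and −0.080 in EYFP-low cells, the basal and squamous keratins median in luminal-like cells, 1.75 in EYFP-low cells, the distal luminal secretory median in basal-like cells, −0.49 under 10% mitochondrial UMIs, and the log2 ratio of Cma1 in macrophage-like cells, −1.35 with doublets kept. In the clustering of NPp53 on its own and in the one under 10% mitochondrial UMIs, 31 NPp53 cells led by Spink5, Ltf and Ccl5 formed a cluster named luminal or basal.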

Other observations

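The comparisons in this part were chosen after the data were seen, and they carry no replicate check. A set of genes was higher in NPp53T in each of 3 recombined populations: EYFP-high cells of the Calcb and Clca1 luminal cluster, EYFP-high cells of the proliferating luminal cluster and EYFP-high basal-like cells. Of 9289 genes measured in all of them, 16 were at least 4-fold higher in each (Lix1, Bglap3, Ly6k, Ceacam10, Ptpn22, Sv2b, Scgb2b27, Eif2s3y, Spink8, Mbd1, Bcl2l15, Gstm1, Adat1, Aebp1, Svs6 and Svs4, the last pair and Ceacam10 being genes of the seminal vesicle) and 6 were at least 4-fold lower (Trim28, Sprr2a3, Tff3, Gsdmc2, Ociad2 and Psca). Lix1 was 58.9-fold higher in the Calcb and Clca1 cluster (2.01 and 118 CPM), 30.5-fold in the proliferating cluster (3.97 and 121 CPM) and 44.9-fold in basal-like cells (12.2 to 374, from 2 and 132 UMIs). Of the 16 genes, 14 were also at least 1.5-fold higher in EYFP-low luminal-like cells with an interval above 1, where free RNA and unmarked recombined cells were not told apart. The exceptions were Gstm1, at a ratio of 1.04, and Aebp1, at 3.91 (0.988 to 33.8). Of the 6 lower genes, 2 were also lower in EYFP-low cells (Sprr2a3, ratio 0.389, and Ociad2, 0.243), Trim28 (0.948) and Gsdmc2 (0.867) lay within 1.5-fold, and Tff3 (2.34-fold, 2.00 to 2.75) and Psca (1.68-fold, 1.55 to 1.82) were higher.

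Mbd1, which encodes a methyl-CpG-binding protein, was 6.58-fold higher (6.17 to 7.02) in EYFP-high luminal-like cells of NPp53T, at 38.5 and 253 CPM, and 8.25-fold in EYFP-high basal-like cells. Its ratio was 1.57 in EYFP-low luminal-like, 1.16 (0.895 to 1.52) in immune-like and 1.07 in fibroblast-like cells. Ptpn22, a phosphatase gene best known from lymphocytes, stood at 2.97 CPM in NPp53 and 47.4 CPM in NPp53T EYFP-high luminal-like cells, against 59.0 and 70.4 CPM in immune-like cells. It lies on chromosome 3 (103859795 to 103912247) close to Bcl2l15 (103832601 to 103854618), another of the 16 genes. Whether Ptpn22 and Bcl2l15 changed independently was not tested. Several of the 16 genes were also higher in immune-like cells, outside the recombined lineage. These were Scgb2b27 (21.9-fold), Svs6 (17.5-fold), Adat1 (5.87-fold, 7 and 70 UMIs), Svs4 (5.48-fold) and Bcl2l15 (3.92-fold). The rule for this set had no filter for free RNA. In NPp53T, immune-like cells held 27.3 CPM of Scgb2b27, against 8.11, 16.8 and 14.0 CPM in the recombined populations, in the order above. Svs6 stood at 21.8 CPM, against 6.75, 8.56 and 9.18, and Svs4 at 66.8 CPM, against 33.4, 30.1 and 44.7. The higher values of Scgb2b27, Svs6 and Svs4 in the recombined populations therefore cannot be told apart from free RNA. With 2 UMIs each in NPp53 immune-like cells, Bglap3 had a ratio of 69.0 (18.9 to 573), Ceacam10 of 6.17 (1.51 to 54.3) and Lix1 of 4.99 (1.19 to 44.6). Among the 6 lower genes, immune-like ratios were 0.0179 for Sprr2a3, 0.0518 for Gsdmc2, 0.0800 for Tff3 and 0.286 for Psca. Ociad2 had 0.320 (0.0973 to 0.945) and Trim28 0.794 (0.636 to 0.994). In NPp53, Tff3 stood at 31.4 CPM in the Calcb and Clca1 population and 35.2 in the basal-like population, against 59.6 in immune-like cells. In the proliferating population Tff3 stood at 1620 CPM in NPp53 and 2.36 in NPp53T. Psca stood in NPp53 at 1106, 287 and 212 CPM in the recombined populations, in the order above, against 25.0 in immune-like cells. Sprr2a3 stood there at 757, 768 and 208 CPM, against 51.2. Gsdmc2 stood at 168, 71.4 and 238 CPM, against 10.6, and Ociad2 at 35.1, 22.5 and 24.1, against 3.43. For Psca, Sprr2a3, Gsdmc2 and Ociad2 these values argue against free RNA at the immune-like level as the whole cause. How much free RNA the recombined cells took up was not tested. For Tff3 in the Calcb and Clca1 and the basal-like populations, free RNA and a change within recombined cells were not told apart.

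Eif2s3y, a gene of the Y chromosome that encodes a translation initiation factor subunit, was 8.04-fold higher (6.84 to 9.51) in EYFP-high luminal-like cells of NPp53T, at 5.98 and 48.1 CPM. Other Y-linked genes lay within 1.5-fold there, with ratios of 1.07 for Ddx3y, 0.954 for Uty and 0.817 for Kdm5d. In EYFP-low luminal-like cells the ratio of Eif2s3y was 1.85, and in immune-like cells 1.45 (1.15 to 1.85, 31.2 and 45.3 CPM). Among the latter, macrophage or monocyte-like cells had a ratio of 1.90 (1.34 to 2.73, 43 and 150 UMIs), so the gene was also higher outside the recombined lineage. No explanation was tested for this gene.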
